A study of Mus musculus with 10 samples.

How the data were processed

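Gene expression was measured on 10 Affymetrix Mouse Genome 430 2.0 arrays, 1 per culture of primary cerebellar granule cell precursors. Per the submitters' culture notes, the cells came from pups at postnatal days 5 to 7, were grown for 24 hours in medium with 20 mM KCl and 10% fetal calf serum, and received sonic hedgehog (Shh) for 24 hours where applicable. The concentration is labelled as 3 mg/ml and is given here as labelled. The labels do not state whether untreated cultures were kept for the same total time as treated ones. Each array was made from 1.5 micrograms of total RNA. The 4 groups were wild type untreated (3 arrays), Bmi1 knockout untreated (3), wild type with Shh (2) and Bmi1 knockout with Shh (2). The submitters call the cultures biological replicates. How many animals went into each culture is not given in the sources used here, so the p-values measure only the spread between these arrays. The treatment note of wild type replicate 3 mentions Shh with the words "if applicable", while its title and characteristics are those of an untreated culture, and it was used as untreated.

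The deposited values are array signal intensity on a linear scale that the authors made with MAS5, and per the submitters' processing notes GCOS 1.2 was used. Every array in the deposited table had a 2% trimmed mean of 500, so the arrays were used as deposited. The table held 45101 probe sets and no detection calls. The number of arrays limits the precision.

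Of the probe sets, 64 controls were left out. Among the others, 34958 carried 1 gene symbol, 932 carried several and 9160 had no gene listed. Of the probe sets with 1 symbol, 34754 were matched by Entrez identifier to the RefSeq annotation of GRCm38.p6, which changed 0 symbols. These probe sets named 18194 genes. Signals below the 25th percentile of all values (20.9, or 4.39 on the log2 scale) were raised to it, and log2 was taken. Each gene was represented by its probe set with the highest mean over all 10 arrays. Genes were tested if that mean was at or above the median of all probe sets (log2 6.25, a signal of 76.1), which left 11405 genes.

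A model with 1 mean per group was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, default prior), with 6 residual and 3.11 prior degrees of freedom. All 10 arrays entered the fit, so that groups with 2 arrays shared the estimate of spread with the others. The 7 comparisons were the genotype effect without and with Shh, the Shh effect in each genotype, their interaction, and the average genotype and Shh effects. Tests were two-sided, Benjamini-Hochberg adjustment ran over genes within a comparison, and the threshold was an adjusted p of 0.05. Errors are the standard errors of the model (SE) unless given as SD. A gene at the floor on every array of 1 group has only a lower bound on its fold, computed from the floor and the mean of the other group. Where only some arrays of the dimmer group lay at the floor, the fold is a lower bound too.

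The running numbers are unique, and the labels name no pairs. Arrays with consecutive numbers (wild type then knockout) deviated together from their group means, with correlations over genes of 0.120 to 0.278 in the 3 untreated pairs against -0.265 to 0.0529 for other untreated pairings. With 2 arrays per group the Shh arrays give only 1 independent value, 0.160 for both pairs and its negative for the crossed ones. All 6 untreated arrays correlated best with their consecutive partner. These are not 6 independent results, because the deviations of the 3 arrays of a group sum to 0. As every pair lay over 0.1, the numbers were taken to pair the cultures, a pairing that comes from the data alone and was settled before any paired fit was run. The fit above carries no block. A second fit, chosen after the data were seen, added the pairs as a fixed factor for the 2 genotype effects, their average and the interaction, which left 3 residual degrees of freedom. The Shh effects lie between pairs and were fitted again with a consensus correlation of 0.289 within pairs. Estimates are the same in both fits, and values from the second are called blocked.

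Before the data were examined, 33 gene lists were fixed, covering the Shh, p53, bone morphogenetic protein (BMP), Notch and Wnt pathways, cell cycle phases, CDK inhibitors, Polycomb members, Hox genes, adhesion and matrix genes, stress and metabolic pathways, ribosomal proteins, sex chromosome markers, stages of granule cells, and markers of other cell types the cultures could hold. The 30 lists with at least 4 tested members were tested with camera at a preset correlation of 0.01, adjusted over the lists within a comparison. Camera with an estimated correlation and fry were run beside it. A list is said to pass by camera with the preset correlation unless another test is named. Camera compares a list with all other genes, whereas fry asks whether the members of a list move on balance in 1 direction. Members were also counted when adjusted over the list alone. Some genes belong to more than 1 list, as Cdkn1a does to the p53 targets and the CDK inhibitors and Igf2 to the Shh pathway targets and the fibroblast markers. In none of the lists that passed did the median, the mean and the direction of the test differ in sign. Among the lists that did not pass, they differed in 1 of 11 for Shh in wild type, in 2 of 12 for Shh in knockout cells, in 5 of 21 and 4 of 18 for genotype without and with Shh, in 5 of 19 for the interaction, and in 6 of 18 and 3 of 12 for the average genotype and Shh effects.

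The rule for named genes was also fixed before the data were examined. It took 13 fixed genes (Bmi1, CDK inhibitors, Shh targets, Atoh1 and Neurod1), the 8 largest rises and 8 largest falls per comparison among genes past the threshold whose groups did not overlap and that lay above the floor on at least 1 array of each group, up to 4 members of each list by p among those that passed (2 if none did), and the 6 genes with the smallest p where fewer than 5 passed. Genes named outside it are described as chosen after their values were seen.

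The procedure was tested on simulated data of the same design, in which 200 of 11405 genes were changed. Of genes changed by 1 on the log2 scale, 77.6% were found for genotype without Shh, 74.6% for genotype with Shh, 77.6% for Shh in wild type, 79.1% for Shh in knockout cells and 46.3% for the interaction. For the average effects this was 85.1% for genotype and 83.6% for Shh. Of genes changed by 0.5, 38.8% were found for genotype without Shh and 1.49% for the interaction. Unchanged genes made up 2.65% to 6.62% of the calls. A list shifted by 0.5 was called in all 7 comparisons, and 0 of 29 unshifted lists were called in each. The simulated genes and arrays were drawn independently. The simulation therefore does not show how often lists or genes are called wrongly when genes are correlated or arrays are paired.

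The alternatives were quantile normalization, scaling of the arrays to the same median, no filter on dim genes, a filter keeping the upper part of the probe sets, no floor, a pseudocount of 32, testing every probe set, the mean of all probe sets of a gene, array weights, a trended and robust prior, fits on only the arrays compared, and leaving out each array in turn. A covariate for sex, read from Xist and Eif2s3y, and a fit without the arrays with high 18S ribosomal RNA signal were chosen after the data were seen. Figures were drawn with matplotlib 3.10.9.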

Results

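Transcript levels were measured in primary cultures of mouse cerebellar granule cell precursors, the dividing cells that give rise to cerebellar granule neurons and whose main mitogen is the secreted protein sonic hedgehog (Shh). Cultures were wild type or lacked Bmi1, a member of Polycomb repressive complex PRC1 that holds down the Cdkn2a locus, and were left untreated or given Shh. There were 3 untreated and 2 Shh-treated arrays per genotype, and these numbers limit the precision of every comparison. Replicates carry the numbers 1 to 10, odd for wild type and even for knockout, with 7 to 10 treated with Shh. A second fit treated consecutive numbers, 1 of each genotype, as pairs. Its values are given as blocked where they changed a call. The title of the series names the role of Bmi1 in the response to Shh as its subject. Each array had a trimmed mean signal of 500, while the median signal was 84.4 to 90.9 on untreated and 66.6 to 72.1 on Shh-treated arrays. The first principal component held 70.1% of the variance and separated Shh-treated from untreated arrays, and the second held 7.79%. The ratio of 3' to 5' control probe sets was 0.823 to 0.997 for Gapdh and 1.34 to 1.69 for Actb. The 18S ribosomal RNA control read 6301 on knockout untreated replicate 6 and 2030 on wild type untreated replicate 1, against 219 to 649 on the other arrays. Xist exceeded the Y-linked gene Eif2s3y on replicates 1, 2, 3, 6 and 8 and lay below it on the other 5, which include both Shh-treated wild type arrays.

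Both Bmi1 probe sets gave signal in knockout cells close to the wild type level. By 1 probe set the signal was 3958 ± 290 (SD, n = 3) in wild type and 3610 ± 259 in knockout untreated cultures, and 4340 ± 248 (n = 2) and 3424 ± 11.8 with Shh. By the other it was 2062 ± 290 and 1941 ± 310 untreated and 2299 ± 363 and 2146 ± 103 with Shh. Averaged over both conditions, knockout cells had 84.9% of the wild type level by the first probe set (95% interval 77.1 to 93.4%) and 93.9% by the second (76.0 to 116%), with an adjusted p of 0.186 for the gene. The deleted part of the gene is not given in the sources used here, so these probe sets may lie outside it and do not check the genotype.

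**Figure D1:**
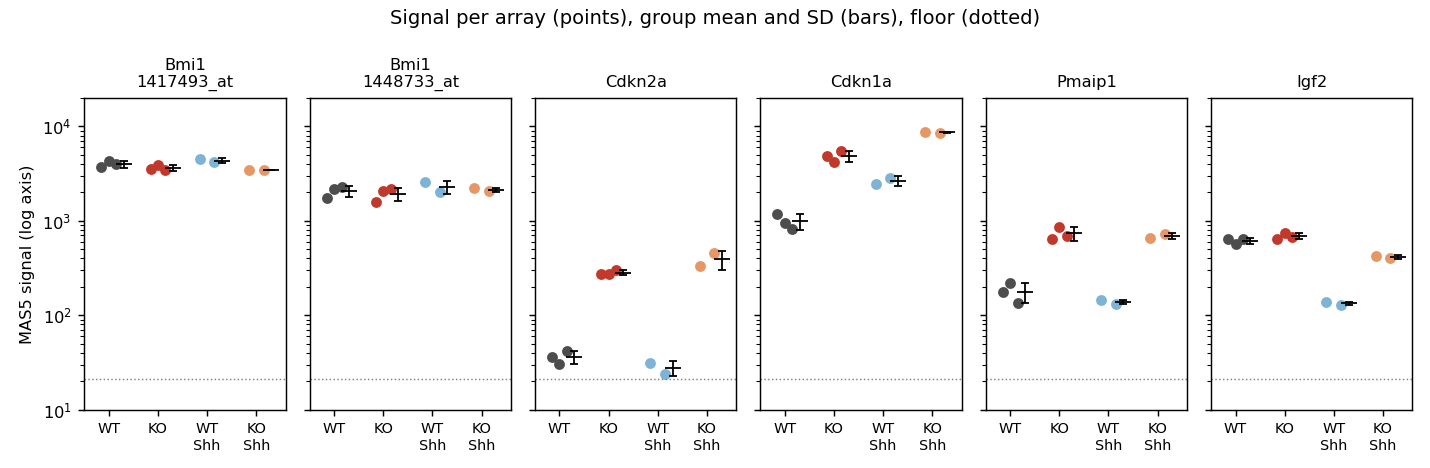
MAS5 signal on a log axis for both Bmi1 probe sets and for Cdkn2a, Cdkn1a, Pmaip1 and Igf2, with 1 point per array, bars for the group mean and SD, and a dotted line at the floor of 20.9. Cdkn2a lies between 271 and 451 on the 5 knockout arrays and between 24.0 and 41.6 on the 5 wild type arrays.

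The comparison of untreated cultures asked which transcripts differed without Bmi1 in cells that received no Shh. Cdkn2a, which encodes the cell cycle inhibitor p16Ink4a and the p53 activator p19Arf, was 7.92-fold higher in knockout than in wild type cultures (log2 2.98, SE 0.16, adjusted p = 9.56e-05, n = 3 per genotype). Targets of p53 rose with it, led by the cell cycle inhibitor Cdkn1a at 4.94-fold (log2 2.30, SE 0.15), the apoptosis gene Pmaip1 at 4.24-fold (2.08, SE 0.18), the death receptor Eda2r at 2.72-fold (1.45, SE 0.09) and the Akt inhibitor Phlda3 at 2.47-fold (1.31, SE 0.11). Of 22 p53 targets tested, 9 rose and 0 fell, and 12 rose when adjusted over the list alone. The list was higher (median log2 0.53, camera adjusted p = 3.94e-18, and adjusted p = 0.00176 with an estimated correlation, blocked 0.113). In the blocked fit 9 members rose, 13 did over the list alone, and the call with the preset correlation held. With an estimated correlation, no list passed in that fit for either genotype effect, their average or the interaction. Such blocked values cannot tell a lost shift from too few residual degrees of freedom. Among the 7 CDK inhibitors, Cdkn2a and Cdkn1a rose and the list median was 0.03 (adjusted p = 0.00415, blocked 0.0629, and adjusted p = 0.213 with an estimated correlation). Cdkn1b, with a log2 difference of -0.37 (adjusted p = 0.358), and Cdkn2c, at 0.03, did not pass.

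Other large rises in untreated knockout cells were those of Igf2bp1, an RNA-binding protein of fetal tissues, at no less than 7.67-fold (log2 2.94, SE 0.37, adjusted p = 0.0109), the transcription factors Lhx2 at 4.34-fold, Dmrta2 at 3.54-fold and Onecut2 at 3.54-fold, and the cardiac actin Actc1 at 3.91-fold. Robo3, an axon guidance receptor chosen after its values were seen because it lay at the floor on every wild type untreated array, was at least 27.7-fold higher (adjusted p = 6.51e-06). The 6 genes that fell were Tmem51 (log2 -1.17, SE 0.18), the glucocorticoid-activating enzyme Hsd11b1 (-1.12, SE 0.15), the calcium channel subunit Cacna2d3 (-0.90, SE 0.10), the fatty acid desaturase Scd1 (-0.84, SE 0.11, with -0.50 on its other probe set), Rasd2 (-0.71, SE 0.11) and St6galnac4 (-0.54, SE 0.08, with 0.04 on its other probe set). With each array left out in turn, Cdkn2a, Cdkn1a, Pmaip1, Eda2r, Phlda3, Lhx2, Dmrta2, Onecut2 and Cacna2d3 kept their calls. Igf2bp1 lost its call without replicate 1, 2 or 6, Actc1 without 1, 5 or 6 (adjusted p up to 0.0752 for both), and Scd1 without 5 or 6 (up to 0.0765). Hsd11b1 lost it without 1, 2, 3, 5 or 6 (up to 0.0857). Tmem51 lost it without any array but 3 (up to 0.164), Rasd2 without any but 2 (up to 0.158), and St6galnac4 without any of the 10 (up to 0.135). Dmrta2 (blocked adjusted p = 0.0616), Actc1 (0.0919), Tmem51 (0.156), Hsd11b1 (0.0915), Scd1 (0.0653), Rasd2 (0.0919) and St6galnac4 (0.0787) did not pass in the blocked fit.

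Genes of cholesterol synthesis were lower as a list in untreated knockout cells, although 0 of 20 passed one by one and 1 (blocked 2) did when adjusted over the list alone (median log2 -0.22, camera adjusted p = 1.44e-08, and adjusted p = 0.0347 with an estimated correlation, blocked 0.450). The sterol dehydrogenase Nsdhl stood at -0.38 (SE 0.08, adjusted p = 0.118). Markers of microglia and macrophages were lower. There were 0 of 19 past the threshold and 5 (blocked 8) when adjusted over the list alone (median -0.45, adjusted p = 1.22e-11, and adjusted p = 0.222 with an estimated correlation). Markers of GABAergic interneurons were higher, with 0 of 9 past and 5 over the list alone, among them the neuropeptide Sst at 1.85 (SE 0.35, adjusted p = 0.0868) and the glycine transporter Slc6a5 at 0.90 (list median 0.44, adjusted p = 0.000134, and adjusted p = 0.139 with an estimated correlation). Shh pathway targets were higher as a list (0 of 16 past, 3 over the list alone, median 0.21, adjusted p = 0.00153, and adjusted p = 0.139 with an estimated correlation), with the pathway effector Gli1 at 0.52 (SE 0.11, adjusted p = 0.113) and the co-receptor Boc at 0.42 (adjusted p = 0.118). Of the other fixed Shh targets, Ccnd1 stood at 0.47, Ptch1 at 0.24, Hhip at 0.20, Ccnd2 at 0.05 and Mycn at 0.01, and none passed. The list of 7 direct Shh targets did not pass (0 past, 3 higher over the list alone, blocked 2, and camera adjusted p = 0.242 with an estimated correlation).

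Fibroblast and meningeal genes were also higher (median 0.22, adjusted p = 0.0391, blocked 0.0570, and adjusted p = 0.222 with an estimated correlation), as were Notch pathway genes (0.10, adjusted p = 0.0303, blocked 0.0570, and adjusted p = 0.222 with an estimated correlation). Genes of maturing neurons and synapses were lower (-0.13, adjusted p = 0.00469, and adjusted p = 0.343 with an estimated correlation). In limma 0 members of these 3 lists passed, and 1 fibroblast gene (blocked 0) did over the list alone. The neuronal list was lost without replicate 4 (adjusted p = 0.120), the fibroblast list without 4 or 5 (up to 0.369), and the Notch list without 1, 4, 5 or 6 (up to 0.141). Genes of DNA replication (median 0.03, adjusted p = 0.476) and of mitosis (0.02, adjusted p = 0.873) did not differ as lists, although the mitotic gene Psrc1 rose (0.76, SE 0.12, adjusted p = 0.036, blocked 0.0535, lost without any array but 2, 7 or 9, up to 0.167). In all, 43 of 11405 genes passed, 37 higher and 6 lower, and their groups of arrays did not overlap. At an unadjusted p under 0.05 there were 990. The count was 25 without replicate 1, 19 without replicate 6, and 10 without both of these arrays, which had the high 18S signal. The blocked count was 23, 21 higher and 2 lower.

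With Shh present, the same question was asked of 2 arrays per genotype. Cdkn2a was 14.1-fold higher in knockout cells (log2 3.82, SE 0.20, adjusted p = 0.000131) and Igf2bp1 at least 13.8-fold (3.78, SE 0.45). The p53 targets Pmaip1 (4.98-fold), Phlda3 (4.78-fold), Eda2r (3.96-fold), Cdkn1a (3.27-fold) and Zmat3 (2.57-fold) rose. Of the 22 p53 targets, 10 rose and 0 fell, 17 rose when adjusted over the list alone, and the list was higher (median 0.85, adjusted p = 2.15e-24, and adjusted p = 0.000743 with an estimated correlation, blocked 0.0639). Further rises were those of Actc1 (8.86-fold), the adenylyl cyclase Adcy8 (5.53-fold), the imprinted gene Zdbf2 (5.11-fold) and Igf2, an imprinted growth factor (3.11-fold, log2 1.64, SE 0.11, adjusted p = 0.000325). Falls were those of Phyhip (log2 -1.43 or lower, SE 0.19), the complement gene C1qa (-1.25, SE 0.16), Hsd11b1 (-1.24 or lower, SE 0.19), Lgals9 (-1.21, SE 0.22), Cmtm7 (-1.17, SE 0.18), Scd1 (-1.09, SE 0.13), the interferon-induced GTPase Irgm1 (-0.96, SE 0.16) and Cacna2d3 (-0.91, SE 0.12). Of these, Hsd11b1 (blocked adjusted p = 0.0767), Cmtm7 (0.0805) and Cacna2d3 (0.0525) did not pass in the blocked fit.

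Interferon and MHC genes were lower in Shh-treated knockout than in Shh-treated wild type cells as a list (0 of 18 past, 0 over the list alone, median -0.40, adjusted p = 6.9e-08, and adjusted p = 0.0108 with an estimated correlation, blocked 0.174), with the antiviral gene Oasl2 at -1.18 (SE 0.34, adjusted p = 0.219). Cholesterol synthesis genes were again lower (0 of 20 past, 6 over the list alone, blocked 3, median -0.29, adjusted p = 2.26e-11, and adjusted p = 0.0108 with an estimated correlation, blocked 0.213). Markers of the oligodendrocyte lineage were higher, with Cspg4 at 1.15 (SE 0.12, with 0.61 on another probe set), Sox10 at 1.28 (SE 0.20, blocked adjusted p = 0.0882, with -0.01 on another probe set) and Olig1 at 0.94 (SE 0.16) past the threshold and 12 others not (7 over the list alone, median 0.54, adjusted p = 2.25e-07, and adjusted p = 0.133 with an estimated correlation). Astrocyte and Bergmann glia markers were higher too, with Gdf10 at 1.09 (blocked adjusted p = 0.121) and Sparcl1 at 0.67 (blocked 0.0794) past the threshold among 21 (4 over the list alone, median 0.24, adjusted p = 5.98e-07, and adjusted p = 0.168 with an estimated correlation). Microglial markers were lower (1 of 19 fell, blocked 2, 5 over the list alone, median -0.39, adjusted p = 1.01e-10, and adjusted p = 0.168 with an estimated correlation).

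Genes of DNA replication were lower as a list with Shh (0 of 49 past, median -0.21, adjusted p = 1.63e-11, and adjusted p = 0.168 with an estimated correlation), and so were genes of mitosis (0 of 53 past, median -0.21, adjusted p = 1.02e-09, and adjusted p = 0.168 with an estimated correlation). Glycolysis genes were lower, with Bnip3 at -0.68 (SE 0.12, blocked adjusted p = 0.122) past the threshold among 17 and 7 over the list alone (median -0.18, adjusted p = 6.86e-07, and adjusted p = 0.121 with an estimated correlation). Shh pathway targets were higher, with Igf2 and the homeobox gene Nkx2-2 (log2 1.24, SE 0.16) past the threshold among 16 (median 0.15, adjusted p = 0.00134, and adjusted p = 0.131 with an estimated correlation). Igf2 and Nkx2-2 both fell with Shh in each genotype. Gli1 stood at 0.04, Ptch1 at 0.18 and Ccnd1 at 0.13, and none of these 3 passed. The list of 7 direct Shh targets did not pass (0 past, camera adjusted p = 0.724 with an estimated correlation). GABAergic markers were higher, with Slc6a5 at 1.60 (SE 0.23, blocked adjusted p = 0.0694) past the threshold among 9 and 4 over the list alone (median 0.50, adjusted p = 0.00255, and adjusted p = 0.167 with an estimated correlation), as were Notch genes (0 of 14 past, 3 over the list alone, median 0.14, adjusted p = 0.00889, and adjusted p = 0.167 with an estimated correlation). The Shh pathway list was lost without replicate 8 (adjusted p = 0.119), and the Notch list without 8 or 9 (up to 0.196).

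In all, 83 genes passed with Shh, 70 higher and 13 lower, their groups did not overlap, and 1113 had an unadjusted p under 0.05. With only the 4 Shh-treated arrays in the fit the count was 3, among them Pmaip1 and Phlda3. It was 54, 29, 32 and 55 without replicates 7, 8, 9 and 10, and 55 without replicate 4. The blocked count was 50, 41 higher and 9 lower. Cdkn2a, Cdkn1a, Pmaip1, Phlda3, Eda2r, Zmat3, Actc1, Zdbf2, Igf2 and Cspg4 kept their calls without any 1 array. Igf2bp1 and Scd1 lost theirs without replicate 8 or 9 (adjusted p up to 0.0642 and 0.0668), Nkx2-2 without 7 (0.0542), and Adcy8 without 7, 8 or 10 (up to 0.0727). Phyhip, C1qa and Hsd11b1 lost theirs without 7, 8 or 9 (up to 0.0914, 0.0904 and 0.124). Cacna2d3 and Slc6a5 lost theirs without 8, 9 or 10 (up to 0.106 and 0.128), Cmtm7 without 7, 8, 9 or 10 (up to 0.130), and Sox10 without 4, 7, 9 or 10 (up to 0.169). The calls of 6 genes held only without certain arrays, and were lost without any other. These were Lgals9 (held without 2 or 6, otherwise up to 0.261), Irgm1 (1 or 5, 0.187), Gdf10 (3 or 10, 0.159), Sparcl1 (1 or 3, 0.200), Olig1 (3 or 5, 0.161) and Bnip3 (3, 0.216).

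Genes called for genotype in untreated cells differed in the same direction with Shh. Of the 43 genes called in untreated cells, 29 were also called with Shh, 25 higher and 4 lower in knockout cells in both. Independent calls would give 0.313, and 0 genes went opposite ways. Both comparisons used the same estimate of spread for each gene, which links their calls, so 0.313 is not the overlap expected by chance. In the blocked fit 17 were called in both, all higher. All 43 had the same sign with Shh, against 60.9% of all 11405 genes. Across all genes, which are not independent replicates, the log2 changes of the 2 conditions had a Pearson r of 0.416 and a Spearman rho of 0.303, and the conditions shared no arrays. Averaged over both conditions, 176 genes passed, 139 higher and 37 lower, with 1479 at an unadjusted p under 0.05. Cdkn2a was 10.6-fold higher (log2 3.40, SE 0.13, adjusted p = 3.63e-06), Igf2bp1 at least 10.3-fold, Actc1 5.88-fold, Pmaip1 4.59-fold and Cdkn1a 4.02-fold. Sst was 3.96-fold higher (log2 1.99, SE 0.27, adjusted p = 0.00853), Lhx2 3.58-fold and Phlda3 3.44-fold. Falls included those of Hsd11b1 (log2 -1.18 or lower, SE 0.12), Phyhip (-1.12 or lower), Ajm1 (-0.98, blocked adjusted p = 0.0632, with -0.01, 0.30 and 0.00 on its other probe sets), Scd1 (-0.96), Cmtm7 (-0.96), Tmem51 (-0.94, blocked adjusted p = 0.0756), Cacna2d3 (-0.90) and C1qc (-0.87).

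On average over conditions, 12 of 22 p53 targets rose and 16 when adjusted over the list alone (median 0.71, adjusted p = 6.17e-23, and adjusted p = 0.000889 with an estimated correlation, blocked 0.0747). In cholesterol synthesis Nsdhl fell (log2 -0.43, SE 0.06, adjusted p = 0.0106), and 12 of 20 genes were lower when adjusted over the list alone (median -0.26, adjusted p = 1.11e-13, and adjusted p = 0.00976 with an estimated correlation, blocked 0.249). Interferon and MHC genes were lower (0 of 18 past, 1 over the list alone, median -0.18, adjusted p = 0.000119, and adjusted p = 0.0395 with an estimated correlation, blocked 0.252). Among 19 microglial markers, C1qa (-0.84), C1qb (-0.87, with -0.43 on another probe set, blocked adjusted p = 0.0876), C1qc and the mannose receptor Mrc1 (-0.63, blocked 0.0876) fell (9 over the list alone, adjusted p = 1.07e-14, and adjusted p = 0.146 with an estimated correlation). Among 9 GABAergic markers, Sst, Slc6a5 (1.25), the GABA-synthesizing enzyme Gad2 (1.19, with 0.18 on its other probe set) and the neuropeptide Npy (1.12, blocked adjusted p = 0.0934) rose (6 over the list alone, adjusted p = 0.000202, and adjusted p = 0.128 with an estimated correlation). Gad2, Mrc1 and Ajm1 lie among the 100 tested genes nearest to Bmi1 on its chromosome, where linked strain DNA was tested for.

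Average shifts were also seen in 7 other lists, all lost with an estimated correlation. Shh pathway targets were higher (median 0.24, adjusted p = 3.83e-05, and adjusted p = 0.0581 with an estimated correlation), with Igf2 and Nkx2-2 past the threshold among 16 and 7 higher over the list alone. Both of these genes fell with Shh in each genotype. The list of 7 direct Shh targets did not pass (0 past, 3 higher and 1 lower over the list alone, camera adjusted p = 0.310 with an estimated correlation). Notch genes (0.22, adjusted p = 0.00275, and adjusted p = 0.136 with an estimated correlation), oligodendrocyte lineage markers (0.18, adjusted p = 0.00671, and adjusted p = 0.31 with an estimated correlation) and astrocyte markers (0.13, adjusted p = 0.0106, and adjusted p = 0.421 with an estimated correlation) were also higher. Replication genes (-0.08), mitotic genes (-0.09, adjusted p = 3.83e-05 for each, and adjusted p = 0.31 with an estimated correlation) and glycolysis genes (-0.07, adjusted p = 0.00157, and adjusted p = 0.251 with an estimated correlation) were lower, although the mitotic genes Psrc1 (0.75) and Ckap2 (0.43) rose. The replication list was lost without replicate 10 (adjusted p = 0.0591), the astrocyte list without 1 or 8 (up to 0.0858), the oligodendrocyte list without 4 or 10 (up to 0.196), and the Ckap2 call without 2, 4, 5, 7, 8 or 9 (up to 0.105).

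Single arrays weighed on these average calls. The count was 98, 116, 103, 107, 84 and 82 without replicates 2, 4, 5, 6, 8 and 9. It was 80 without both arrays of high 18S signal and 97 with sex as a covariate. Of the 34 genes named for this comparison by the rule and called, 22 kept their call without any 1 array. Nsdhl lost its call without replicate 9 (adjusted p = 0.0625), Tmem51 without 7 or 8 (up to 0.0747), Gad2 without 1, 2, 6, 8 or 10 (up to 0.0883), and C1qc without 2, 4, 5, 6, 8 or 9 (up to 0.0989). Calls that held only without certain arrays were those of Ajm1 (6 or 10, otherwise up to 0.152), C1qb (3 or 10, 0.149), Mrc1 (3 or 8, 0.146) and Npy (3, 0.146).

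**Figure D2:**
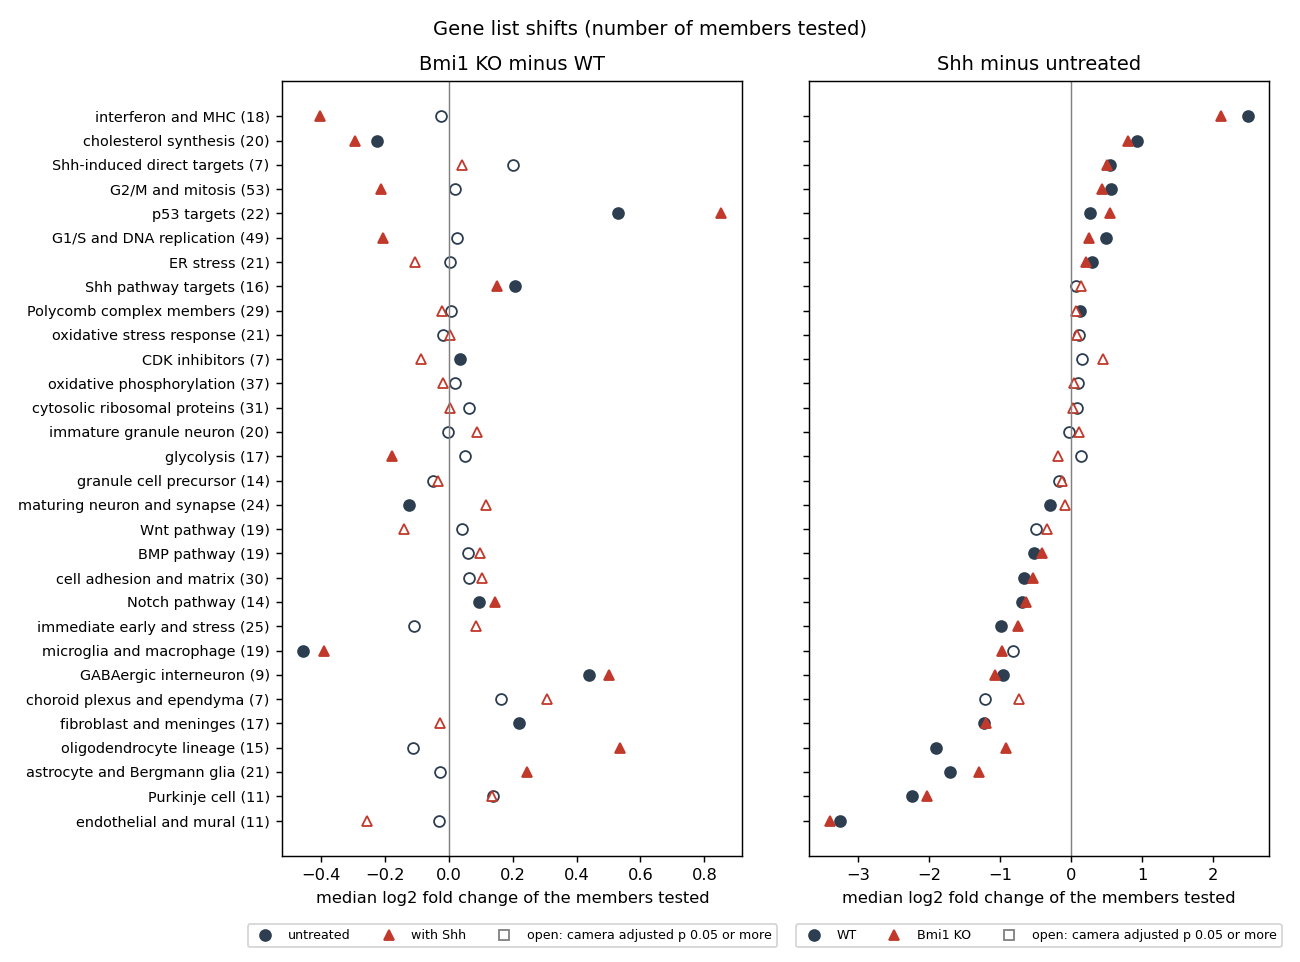
Median log2 change of the members tested in each of 30 gene lists, knockout minus wild type on the left (circles untreated, triangles with Shh) and Shh minus untreated on the right (circles wild type, triangles knockout), with filled symbols where the camera adjusted p was under 0.05. The p53 targets have the highest genotype medians (0.53 and 0.85), and the endothelial and mural markers have the lowest Shh medians (-3.27 and -3.40). With arrays scaled to the same median, the Shh median of the maturing neuron list in wild type cells moves from -0.30 to 0.05.

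The comparison of Shh-treated with untreated cultures asked what differed with Shh in each genotype. The labels do not say whether the time in culture was equal. All Shh-treated arrays carry later numbers than all untreated ones, so any other difference between these sets of cultures cannot be told apart from Shh. In wild type cells, 3855 genes passed (1593 higher and 2262 lower, 5054 at an unadjusted p under 0.05), and 3199 in knockout cells (1260 higher and 1939 lower, 4535 at an unadjusted p under 0.05). The first count was 2380 without replicate 9, and the second was 1893 without replicate 8 and 2045 without replicate 10. How the calls split by direction depended on the scaling. With arrays scaled to the same median signal, the median log2 change of all genes moved to 0.33 in wild type and 0.29 in knockout cells, from -0.01 in both, and the share of calls that were higher moved from 41.3 to 80.6% and from 39.4 to 79.4%. For the average Shh effect, with 5376 genes past the threshold, the median moved to 0.31 and that share from 44.4 to 80.2%. Quantile normalization gave 48.9, 46.1 and 50.7%. Log2 changes below are relative to the trimmed mean of each array and would be higher by about these shifts under the median scaling.

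Direct targets of Shh signalling rose in both genotypes. Gli1 was 2.07-fold higher with Shh in wild type (log2 1.05, SE 0.12, adjusted p = 0.000235) and 1.48-fold in knockout cells (0.57, SE 0.12). The receptor Ptch1 was 1.97-fold (log2 0.98, with 0.48 on another probe set) and 1.89-fold higher, the G1 cyclin Ccnd1 1.81-fold and 1.42-fold, and the growth regulator Mycn 1.46-fold and 1.42-fold. In each genotype 4 of 7 direct targets rose and 0 fell, and 5 when adjusted over the list alone (medians 0.55 and 0.50, adjusted p = 0.00165 and 0.00157, and adjusted p = 0.066 and 0.0708 with an estimated correlation). Ccnd2 stood at 0.37 (adjusted p = 0.053, blocked 0.0465) and 0.36 (adjusted p = 0.0687), the precursor factor Atoh1 at 0.41 (adjusted p = 0.0501, blocked 0.0468) and 0.26 (adjusted p = 0.208), and Hhip, Neurod1, Cdkn1b, Cdkn2c and Cdkn2a did not pass in either genotype. Mycn lost its call in wild type cells without replicate 7 (adjusted p = 0.0848), and in knockout cells without 8 or 10 (up to 0.147). In knockout cells, Gli1 lost it without 8 (0.0633) and Ccnd1 without 2 or 8 (up to 0.174). The wider list of Shh pathway targets went both ways, with 5 rising and 4 falling of 16 in wild type cells (median 0.07, mean -0.11, adjusted p = 0.507) and 4 and 4 in knockout cells (median 0.14, adjusted p = 0.402). Igf2 fell in both genotypes (log2 -2.20, SE 0.10, and -0.74, SE 0.10), as did Nkx2-2 (-1.47 and -0.45, adjusted p = 0.000102 and 0.043).

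Cell cycle genes rose with Shh. Of 49 genes of DNA replication, 37 rose in wild type and 15 in knockout cells, among them the exonuclease Exo1 (log2 1.61 and 1.43), Atad2 (1.40 and 1.06), and the replication factors Mcm10 (1.29 and 0.87) and Cdc45 (1.15 and 0.96). The uracil glycosylase Ung fell in knockout cells (-0.62). Medians were 0.50 and 0.25 (adjusted p = 1.37e-13 and 3.07e-07, and adjusted p = 0.0866 and 0.192 with an estimated correlation). Of 53 mitotic genes, 40 and 29 rose and 0 fell in either genotype, with the kinase Aurka at 1.52 and 1.28, Anln at 1.42 and 1.39 (0.92 and 0.15 on its other probe set) and the kinetochore gene Ndc80 at 1.57 and 1.16 (medians 0.56 and 0.43, adjusted p = 2.67e-18 and 2e-13, and adjusted p = 0.066 and 0.0976 with an estimated correlation). The inhibitor Cdkn1a also rose, by 2.72-fold in wild type and 1.80-fold in knockout cells, and Cdkn2d, an INK4 inhibitor, by 1.81-fold and 1.52-fold, while the list of 7 CDK inhibitors did not pass (adjusted p = 0.112 and 0.111). Cdkn2d lost its call in knockout cells without replicate 2, 4 or 8 (adjusted p up to 0.189). Of 22 p53 targets, 8 rose and 1 fell in wild type (median 0.26, adjusted p = 0.00241, and adjusted p = 0.0523 with an estimated correlation), and 15 rose and 1 fell in knockout cells (median 0.54, adjusted p = 8.61e-07, and adjusted p = 0.00972 with an estimated correlation). Eda2r rose by 0.81 and 1.35 and Gtse1, which is also a mitotic gene, by 1.04 and 1.14, whereas Btg2 fell in both genotypes (-1.31 and -0.85).

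The largest rises with Shh included several interferon-induced genes. Usp18, a brake on interferon signalling, rose at least 96.2-fold in wild type cells (log2 6.59, SE 0.20, adjusted p = 2.06e-07). It rose at least 73.2-fold in knockout cells, where it was at the floor on every untreated array. The chemokine Ccl5 rose at least 70.0-fold and at least 51.6-fold. In wild type and knockout cells, Rtp4 rose 18.2-fold and 8.60-fold, the phagocyte oxidase subunit Cybb at least 16.4-fold and 11.5-fold, and Ifi27 14.6-fold and 7.41-fold. The acute-phase gene Saa3 (18.3-fold), Oas1a (at least 14.4-fold) and Oasl2 (13.7-fold) were among the 8 largest rises in wild type cells, and Mir670hg (12.6-fold), the nuclear receptor Nr4a3 (11.8-fold), the galectin Lgals3 (9.62-fold), the AP-1 member Fosl2 (9.35-fold) and the leukocyte antigen Cd52 (7.67-fold) in knockout cells. Of 18 interferon and MHC genes, 16 rose and 0 fell in wild type (median 2.49, adjusted p = 1.71e-11, and adjusted p = 0.00813 with an estimated correlation), and 13 rose and Ifit2 fell (-0.80) in knockout cells (median 2.11, adjusted p = 7.53e-10, and adjusted p = 0.00882 with an estimated correlation). The list also holds Ifitm3, at 2.62 (SE 0.12) and 2.08 (SE 0.12), and the interferon response factor Irf9, at 2.98 (SE 0.19) and 2.64 (SE 0.19).

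Sterol genes rose as well. Of 20 genes of cholesterol synthesis, 17 rose in each genotype and 0 fell (medians 0.93 and 0.80, adjusted p = 2.01e-12 and 2.17e-12, and adjusted p = 0.0109 and 0.00882 with an estimated correlation), with 19 and 18 when adjusted over the list alone. Msmo1 rose 3.42-fold and 3.05-fold, Lss 2.60-fold and 1.90-fold (log2 1.38 and 0.93, with 0.41 and 0.30 on its other probe set), Nsdhl 2.23-fold and 2.08-fold, and the sterol carrier Stard4 2.14-fold and 2.22-fold.

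Markers of blood vessels showed the largest falls. On the log2 scale in wild type and knockout cells, the apelin receptor Aplnr changed by -6.22 and -6.65 (SE 0.36, with -3.23 and -2.12 on its other probe set), the pericyte gene Rgs5 by -5.75 and -5.58 (SE 0.28), and the endothelial junction gene Cldn5 by -5.10 and -5.52 (SE 0.16). The endothelial receptor Cd93 changed by -4.37 and -4.91 (SE 0.16), the matrix protein Mfap4 by -5.08 and -4.92 (SE 0.20), and the immediate early factor Egr1 by -5.34 and -4.91 (SE 0.29). The brain endothelial transporter Slco1c1 was at least 76.8-fold lower in wild type and at least 69.9-fold lower in knockout cells. Also among the largest falls were those of Col2a1 (-4.17 or lower) in wild type cells and of Slc38a5 (-4.70 or lower) and Ctla2a (-4.56 or lower) in knockout cells. Of 11 endothelial and mural markers, 10 fell in each genotype and 0 rose (medians -3.27 and -3.40, adjusted p = 4.07e-10 and 1.08e-10, and adjusted p = 0.0109 and 0.00882 with an estimated correlation). Fibroblast and meningeal genes fell in 11 and 12 of 17 cases, such as the collagen Col1a2 at -2.59 and -2.99 and Sparc at -1.96 and -1.72 (medians -1.23 and -1.20, adjusted p = 5.4e-06 and 8.56e-08, and adjusted p = 0.0303 and 0.0106 with an estimated correlation). Of 30 adhesion and matrix genes, 17 and 15 fell and 1 and 2 rose, with tenascin Tnc at -3.20 and -2.80 and the laminin Lama4 at -3.77 or lower in wild type and at least 17.8-fold lower in knockout cells (medians -0.66 and -0.54, adjusted p = 1.89e-05 and 2.6e-05, and adjusted p = 0.0499 and 0.0445 with an estimated correlation).

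Markers of other neural cells fell with Shh too. Of 21 astrocyte and Bergmann glia markers 16 fell in each genotype and 1 and 2 rose (blocked 0 and 1), with Gdf10 at -4.10 and -3.08 and Sparcl1 at -2.13 and -1.50 (medians -1.71 and -1.30, adjusted p = 3.56e-09 and 1.65e-07, and adjusted p = 0.0925 and 0.143 with an estimated correlation). Of 15 oligodendrocyte lineage markers 13 and 11 fell and 1 rose, with the myelin gene Cnp at -2.02 and -1.47 (medians -1.91 and -0.92, adjusted p = 1.48e-07 and 0.000343, and adjusted p = 0.076 and 0.16 with an estimated correlation). Of 11 Purkinje cell markers 10 and 9 fell, with Ppp1r17 at -3.84 or lower and -3.16 and Slc1a6 at -3.75 and -4.42 (medians -2.24 and -2.04, adjusted p = 9.92e-07 and 3.07e-07, and adjusted p = 0.15 and 0.144 with an estimated correlation). Of 9 GABAergic markers 7 fell in each genotype, with the vesicular transporter Slc32a1 at -0.96 and -1.07 (adjusted p = 0.00241 and 0.00374, and adjusted p = 0.0964 and 0.137 with an estimated correlation). Microglial markers moved both ways, with 4 rising and 9 falling of 19 in wild type cells (median -0.83, adjusted p = 0.0681, and 0.000967 with arrays scaled to the same median) and 5 and 9 in knockout cells (median -0.97, adjusted p = 0.0242, and adjusted p = 0.578 with an estimated correlation, lost without replicate 8 at adjusted p = 0.0975). The homeostatic receptor P2ry12 stood at -4.07 or lower in wild type cells and was at least 14.5-fold lower in knockout cells, whereas the lysozyme Lyz2 rose by 1.88 and 1.73.

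The list of 14 granule cell precursor genes did not pass in either genotype (medians -0.17 and -0.13, adjusted p = 0.852 and 0.757), with 2 rising, Ptch1 and Mycn (blocked 4 in wild type cells), and 2 falling, Mfap4 and Olfm2, in each. Olfm2 stood at -0.84 and -1.18 and lost its call in wild type cells without replicate 9 (adjusted p = 0.126) and under quantile or median scaling. Of 20 genes of immature granule neurons 1 rose and 6 fell in wild type cells, including the guidance receptors Nrp1 at -1.53 and Dcc at -0.89 (median -0.03, adjusted p = 0.38), and 1 and 5 in knockout cells (median 0.11, mean -0.04, adjusted p = 0.757). Of 24 genes of maturing neurons and synapses 10 fell in wild type cells, such as the calcium sensor Vsnl1 at -2.49 (-1.66 on another probe set) and Cbln3 at -2.05 (median -0.30, adjusted p = 0.0175, and adjusted p = 0.306 with an estimated correlation), while the list median was 0.05 with arrays scaled to the same median. In knockout cells 4 rose and 5 fell (median -0.09, adjusted p = 0.672).

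Of 19 genes of the BMP pathway 9 and 8 fell, among them Id3 at -2.16 and -1.71 and Id4 at -1.98 and -1.30 (medians -0.53 and -0.41, adjusted p = 0.000668 and 0.000864, and adjusted p = 0.0802 and 0.0976 with an estimated correlation). Notch genes fell in 9 and 7 of 14 cases, Notch3 at -2.72 and -2.10 and Hes1 at -1.34 and -0.92 (medians -0.70 and -0.64, adjusted p = 0.00269 and 0.00197, and adjusted p = 0.0802 and 0.0906 with an estimated correlation). Of 29 Polycomb members other than Bmi1, 7 rose in wild type and 3 in knockout cells, with Mtf2 at 0.81 (0.53 on another probe set) and 0.99 and Eed at 0.62 and 0.58. The Polycomb list passed in wild type cells (median 0.12, adjusted p = 0.0271, and adjusted p = 0.151 with an estimated correlation), except without replicate 3 or 9 (up to 0.0639) or with quantile normalization (0.0528). It did not pass in knockout cells (adjusted p = 0.0852).

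**Figure D3:**
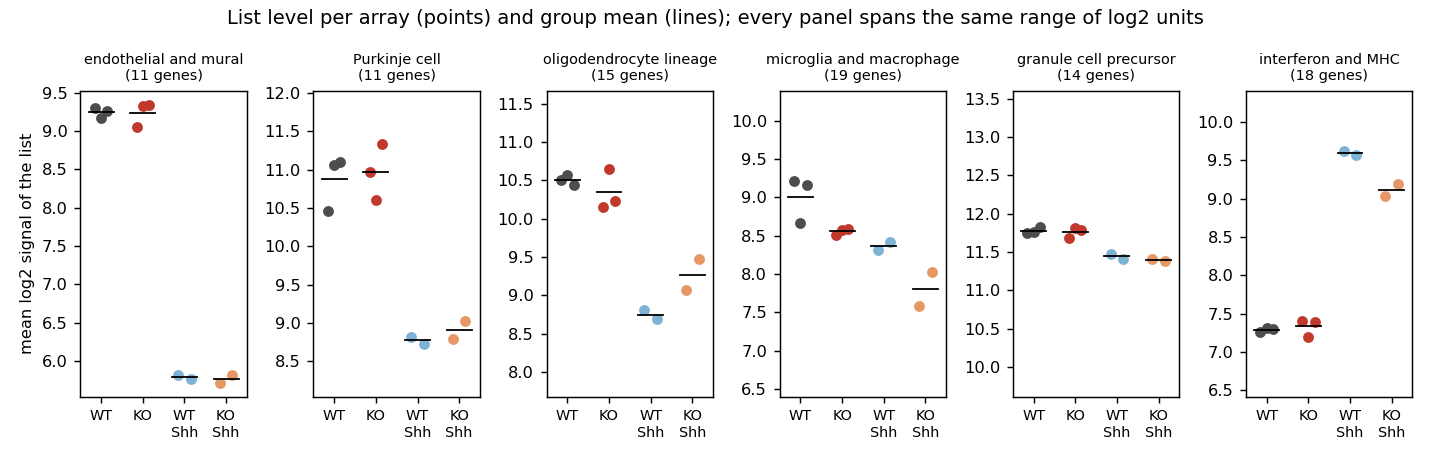
Mean log2 signal of the tested members of 6 lists, 1 point per array and a line at each group mean, with panels of equal height in log2 units. The endothelial and mural, Purkinje cell and oligodendrocyte lineage levels lie lower on all 4 Shh-treated arrays than on all 6 untreated arrays, and the interferon and MHC level lies higher.

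Adjusted over each list alone, the numbers that rose with Shh in wild type and knockout cells were 41 and 17 for replication genes, 45 and 34 for mitotic genes and 8 and 16 for p53 targets. The numbers that fell were 12 and 13 for fibroblast genes, 18 and 17 for adhesion genes, 11 and 10 for Purkinje cell markers, 8 and 7 for GABAergic markers and 11 and 8 for BMP genes. Counts were the same as over all genes for interferon, astrocyte, oligodendrocyte, microglial, Notch and Polycomb genes.

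Changes with Shh mostly had the same direction in both genotypes. Any other difference between the earlier and later numbered cultures would enter both Shh effects alike and raise this agreement. Of the genes called, 2597 were called in both genotypes, 980 higher and 1615 lower in both, and 2 went opposite ways. Independent calls would give 1081, but the shared estimate of spread of each gene links the calls here too. Across genes, which are not independent replicates, the log2 changes had a Pearson r of 0.914 and a Spearman rho of 0.863. Among genes called in wild type cells, 98.8% had the same sign in knockout cells, against 84.6% of all genes. Differences in size remain possible, as 1.49% of simulated interactions of 0.5 on the log2 scale were found.

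**Figure D4:**
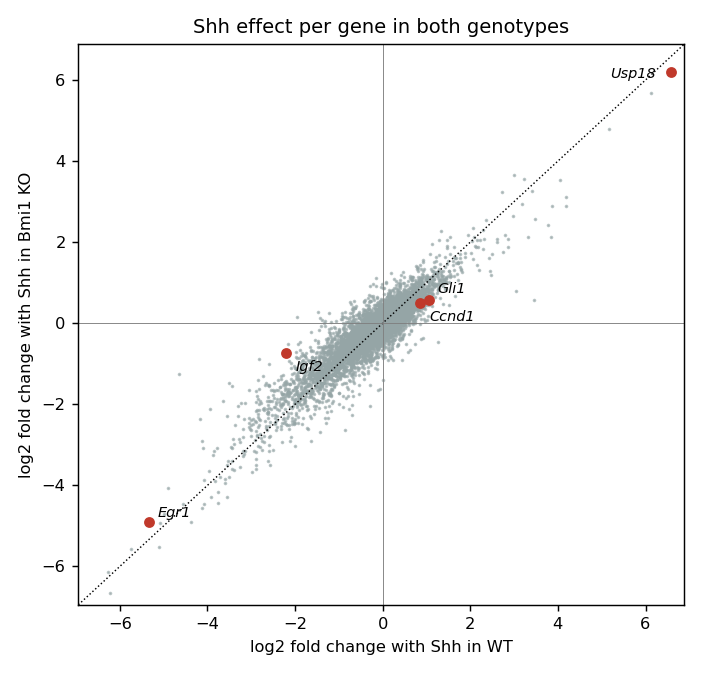
Log2 change with Shh in knockout cells against that in wild type cells, 1 point per tested gene, with a dotted line of equality. Igf2 (-2.20 and -0.74) lies off the line, and Gli1, Ccnd1, Egr1 and Usp18 are marked.

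The interaction asked whether Bmi1 changes the response to Shh, and 1 gene passed in limma. Igf2 fell less with Shh in knockout than in wild type cells, a difference of 1.46 on the log2 scale (SE 0.15, adjusted p = 0.0382, blocked 0.387, where limma called 0 genes), with 561 genes at an unadjusted p under 0.05. Its call was lost without any 1 of the 10 arrays (adjusted p up to 0.297) and with quantile normalization, median scaling or a pseudocount of 32. The next genes by p did not pass (adjusted p = 0.444 each), and were Adgra1 (1.59), Plaat1 (-0.98), Adgrb2 (0.73), Fndc1 (1.21 or higher) and Sgsm1 (-1.29). Gli1 had an interaction of -0.48 (SE 0.17, adjusted p = 0.902), Ptch1 of -0.06 and Ccnd1 of -0.35, so a different response of these targets was not shown. The p53 targets responded more to Shh in knockout cells as a list (median 0.24, adjusted p = 2.95e-05, and adjusted p = 0.04 with an estimated correlation, blocked 0.257), and interferon and MHC genes less (median -0.43, adjusted p = 2.61e-06, and adjusted p = 0.04 with an estimated correlation, blocked 0.257), although 0 members of either list passed in limma. Over the list alone 1 p53 target and 0 interferon genes did. The p53 target Cdkn1a went against its list, with a log2 change with Shh of 1.44 in wild type and 0.85 in knockout cells. Another 9 lists passed with the preset correlation, and none of these did with the estimated one.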

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

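Of the tests below, those of a common dilution, of array scaling, of time in culture, of more microglia and of linked strain DNA were chosen only after the result was seen, and so was the requirement that an interval lie below 0 in the test of toll-like receptor targets. The condition that a result near Bmi1 hold in the blocked fit also came after the result, and the test of a common dilution was first made against the microglial list alone (difference -2.29, permutation p = 0.0125).

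Markers of blood vessels, glia, Purkinje cells and interneurons were lower in Shh-treated cultures of both genotypes, and loss of these cells during treatment could explain this. To test 1 common dilution of all other cell types, the endothelial and mural median was compared with those of 6 lists. It lay further down than the fibroblast and meningeal median (difference -1.90, permutation p = 0.0130 after multiplying by the 6 lists compared). For the average Shh effect 0 markers of either list rose, but 1 endothelial marker rose in knockout cells when adjusted over the list alone. Against Purkinje cell and GABAergic markers the permutation p was 0.0473 and 0.0124 before that multiplication, and did not pass after it. The permutation shuffled markers, not cultures. Markers with signal from other cells fall less under the same dilution, so a common dilution was not excluded. Scaling was excluded as the source, because the endothelial median was -3.02 with arrays at the same median and -3.08 after quantile normalization. A longer time in culture of the treated arrays remains possible, since immediate early genes, which dissociation induces, had a median of -0.83 with 13 of 25 lower and 2 higher (adjusted p = 0.565 with an estimated correlation), and the labels do not separate time from Shh. Cell counts or vessel staining in cultures kept for equal times would separate loss of cells from repression.

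Interferon and MHC genes were higher in Shh-treated cultures, with a median log2 change of 2.40 over both genotypes (16 of 18 rose). More microglia or macrophages could carry such genes, but their markers had a median of -0.90 and not near the interferon median (permutation p = 1e-05, the smallest value possible here), which excluded more such cells of unchanged profile, while a change of their state stays open, as 5 markers rose and 10 fell. An innate immune stimulus in the Shh preparation, such as endotoxin, might act through toll-like receptors. Of 20 tested toll-like receptor and NF-kappaB targets, Cxcl16 (1.26) and Tnfaip2 (0.99) rose and 6 fell, with a median of -0.0749 (95% bootstrap interval -0.65 to 0.31, p = 0.933 with an estimated correlation), and as the interval spans 0 the test left this explanation open. The first version of the test asked only for a median at or below 0, which would have excluded it.

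Among genes that depended on genotype those near Bmi1 were over-represented, since 6 of the 100 nearest tested genes passed for the average genotype effect, against 170 of 11272 elsewhere (6% and 1.51%, one-sided Fisher exact p = 0.00453), but in the blocked fit 2 passed near it and 138 elsewhere (p = 0.349). Strain DNA linked to the Bmi1 allele predicts such a cluster, and Arhgap21, Thnsl1 and Gad2 were higher and Mrc1, Ajm1 and Qsox2 lower in knockout cells, with Thnsl1 (adjusted p = 0.0690), Mrc1 (0.0876), Ajm1 (0.0632) and Qsox2 (0.0848) lost in the blocked fit. By distance from Bmi1, Arhgap21, Thnsl1, Gad2 and Mrc1 stood at places 12, 14, 17 and 20 of the 100, and Ajm1 and Qsox2 at 63 and 77. These places were not tested. General clustering of called genes along chromosomes was left open as well, because 0.648% of other windows held as many (highest 7, median 1) but 33.1% did in the blocked fit. The probe sets differed for Arhgap21 (0.73 on the main and 3.41 on the second), Ajm1 (-0.98 on the main and -0.01, 0.30 and 0.00 on the others) and Gad2 (1.19 and 0.18), as a sequence difference under probes could cause. Gad2 and Mrc1 belong to the GABAergic and microglial lists, so those 2 calls may not reflect cell numbers, and genotyping of strain markers around the locus would settle it.

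The Shh response differed between genotypes by the interaction test for Igf2 (log2 1.46, blocked adjusted p = 0.387) and, by camera with the preset correlation only, for the following lists. Genes of DNA replication had an adjusted p of 1.05e-12 (median -0.25, and adjusted p = 0.201 with an estimated correlation). Mitotic genes had an adjusted p of 1.47e-09 (-0.18, and adjusted p = 0.257 with an estimated correlation). Oligodendrocyte lineage markers had an adjusted p of 3.65e-11 (0.55, and adjusted p = 0.0927 with an estimated correlation). For astrocyte and Bergmann glia markers it was 2.47e-09 (0.45, and adjusted p = 0.201 with an estimated correlation). For glycolysis genes it was 1.85e-07 (-0.26, and adjusted p = 0.0927 with an estimated correlation). For maturing neuron and synapse genes it was 1.97e-05 (0.22, and adjusted p = 0.201 with an estimated correlation). Immature granule neuron genes gave 0.00351 (0.12, and adjusted p = 0.56 with an estimated correlation), lost without replicate 5 or 10 (up to 0.0539). Immediate early and stress genes gave 0.0341 (0.28, and adjusted p = 0.716 with an estimated correlation), held only without replicate 2 or 5 (otherwise up to 0.603). Cholesterol synthesis genes gave 0.0354 (-0.09, blocked 0.0787, and adjusted p = 0.277 with an estimated correlation), lost without replicate 3, 4, 5, 8, 9 or 10 (up to 0.214). Interferon and MHC genes (2.61e-06) and p53 targets (2.95e-05) passed with both correlations, except in the blocked fit with the estimated one (adjusted p = 0.257 for both).

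The 18S ribosomal RNA control of knockout untreated replicate 6 read 6301, against 2030 on the next highest array.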

How the results depend on the processing

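The blocked fits, the fits with sex as a covariate and without the 2 arrays of high 18S signal, and the 8 list results followed most closely, were chosen only after the result was seen. Of 14464 planned values for named genes, 13823 kept the same status, called or not, 505 lost a call, 134 gained one and 2 were reversed. Of 4549 for the other lists, 4224 kept it, 160 lost it, 164 gained one and 1 was reversed. The Bmi1 level kept its result in 20 of 20. Named genes that were called and kept the call in every alternative set before the data were seen were 9 of 17 for genotype untreated, 2 of 28 with Shh, 20 of 34 on average, 0 of 1 for the interaction, 102 of 119 for Shh in wild type, 92 of 115 in knockout cells and 114 of 125 on average. For lists, these were 2 of 9, 3 of 12, 3 of 12, 2 of 11, 5 of 19, 6 of 18 and 6 of 18. For genotype untreated (43 genes) the count was 65 with array weights, 82 with a trended and robust prior and 10 without the 18S arrays. For genotype with Shh (83) it was 51 with quantile normalization, 134 with the trended prior, 3 with only the arrays compared, 43 with sex and 52 without the 18S arrays. Median scaling gave 6423 for Shh in WT (wild type, 3855) and 5475 for Shh in KO (knockout, 3199), by construction, as it moves all genes up with Shh. The interaction (1) gave 0 with quantile normalization, median scaling, a pseudocount of 32, every probe set, mean of probe sets, sex or without the 18S arrays, 8 with no filter and 2 with no floor. The average genotype effect (176) gave 97 with sex and 80 without the 18S arrays. With no filter the agreement r fell to 0.813 for Shh (0.914) and 0.263 for genotype (0.416). With an estimated correlation the average Shh effect had an adjusted p of 0.0676 for direct targets and 0.0825 for mitotic genes. Leaving out 1 array gave 19 to 50 genes for genotype untreated, 29 to 91 with Shh, 0 to 2 for the interaction, 82 to 219 for average genotype, 4491 to 5246 for average Shh, 2380 to 3752 for Shh in wild type and 1893 to 3193 in knockout cells, and r of 0.884 to 0.909 for Shh and 0.328 to 0.435 for genotype. When the upper part of the probe sets was kept, the GABAergic list for genotype with Shh lost its call and the direction of its test turned (adjusted p = 0.978), with a median still at 0.05. Reversed was Nfe2l2 with the mean of probe sets (-0.69 for Shh in knockout cells, -0.66 on average). Without the 18S arrays, the test direction turned for the Purkinje cell list untreated (adjusted p = 0.000138, median -0.31) and for the immediate early and stress list untreated (0.029, median 0.26), in the interaction (0.452, median -0.09) and in the average genotype effect (0.0289, median 0.16), and 2 pairs lost an array. In the replicate block fits of consecutive numbers the count was 23 for genotype untreated, 50 with Shh and 0 (limma) for the interaction. Besides the calls given as blocked beside their results, the block lost Nefm (adjusted p = 0.0920), Sox10 (0.0900) and Col6a3 (0.0509) for average genotype and Ndufb3 (0.0807) and Ndufa4 (0.0651) for average Shh. It gained Sesn2 with Shh (0.0428) and on average (0.0189), and Timp2 (0.0406), Notch3 (0.0487) and Apcdd1 (0.0306) for average genotype. Lists gained were immediate early genes untreated (0.0130), choroid plexus for average genotype (0.0347) and average Shh (0.0491), and microglia for average Shh (0.0458). The block changed no other call of a named gene or a list. Except for the median scaling, the cause was not tested. A group left with 1 Shh array was assumed to vary like the others.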

Other observations

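The tests of splits and of sex below were set before their results were seen, and the sex covariate itself and the count of splits that keep pairs were chosen only after the result was seen.

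Immediate early and stress genes were lower with Shh in both genotypes, with Egr1 at -5.34 and -4.91, Klf2 at -2.88 and -3.36 and Zfp36 at -3.47 and -3.04 in wild type and knockout cells, whereas Fosl2 rose by 2.73 and 3.22. Of 25 genes, 11 and 10 fell and 1 rose (medians -0.99 and -0.76, adjusted p = 0.00241 and 0.0328, and adjusted p = 0.463 and 0.613 with an estimated correlation). The knockout list was lost without replicate 2 or 8 (up to 0.170). Genes of the ER stress response rose in 7 of 21 cases in each genotype, such as the asparagine synthetase Asns at 0.91 and 0.95 and Atf5 at 1.12 and 1.29 (medians 0.29 and 0.21, adjusted p = 0.00241 and 0.00497, and adjusted p = 0.0523 and 0.0708 with an estimated correlation).

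With the arrays as deposited, the other lists did not pass by camera for Shh in either genotype. Fry, which asks another question, passed more lists, 27 of 30 for Shh in wild type and 23 of 30 in knockout cells. With arrays scaled to the same median, the Wnt (adjusted p = 0.019 and 0.0147), choroid plexus (0.00787 and 0.013) and oxidative phosphorylation (0.00787 and 0.0225) lists passed in both. In the oxidative stress list, 6 of 21 genes rose, including Hmox1 at 1.61 and 1.53, and 2 fell, including Gpx3 at -2.02 and -1.23 (adjusted p = 0.133 and 0.0736). Of 17 glycolysis genes, Hk2 rose by 0.84 and 0.64 and Slc2a1 stood at -0.72 (-0.46 on another probe set) and -0.98, with 6 rising and 3 falling in wild type and 1 and 6 in knockout cells (adjusted p = 0.127 and 0.307). Of 19 Wnt genes, Apcdd1 stood at -2.23 and -1.53 (-1.32 and -0.76 on another probe set) and Axin2 rose by 0.59 and 0.69 (9 and 7 fell and 3 rose, adjusted p = 0.14 and 0.098). Choroid plexus and ependymal markers gave an adjusted p of 0.0801 and 0.098, with Tmem212 at -2.59 or lower and -2.54 or lower, a call lost in wild type cells without replicate 3 or 9 (up to 0.140) and in knockout cells without 4 or 10 (up to 0.168). Oxidative phosphorylation genes (medians 0.09 and 0.05, adjusted p = 0.105 and 0.307) and ribosomal protein genes (0.08 and 0.03, adjusted p = 0.15 and 0.582) held near 0, with Rpl14 (0.64) rising in wild type cells unless replicate 9 was left out (adjusted p = 0.0688). Lists too small for a test were the erythroid list with 3 genes tested, where Alas2 fell (-2.05 and -1.64, lost in knockout cells without replicate 10 at adjusted p = 0.0569), the sex chromosome markers with 3, and the Hox genes with 1, Hoxa5, at 0.70 for the average genotype effect (adjusted p = 0.07).

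Splits of the same arrays into other groups were used to ask how often as many genes would pass. For the average genotype effect the real grouping was the only 1 of 60 to give 176 genes, with 11 at most in any other, and for the average Shh effect it was the only 1 of 100 to give 5376, with 0 in any other. For genotype untreated it was the only 1 of 10 to give 43, with 1 at most in any other, and 10 splits are too few for a share under 0.05. Over all splits, which leave the pairs out of account, the share was under 0.05 for both average effects. Every other Shh split mixes treated and untreated arrays in a group, which adds the large Shh difference to the spread. A low count there was thus largely fixed in advance. It also says nothing of other differences between the earlier and later numbered cultures. Of the splits that treat the pairs of consecutive arrays as the real one does, 16 for the average genotype effect, 10 for the average Shh effect and 4 for genotype untreated, the real one alone gave as many genes. The others gave at most 11, 0 and 0, and splits that treat the pairs differently gave at most 5, 0 and 1. The splits that keep the pairs are too few for a share under 0.05, so with the pairs kept chance was not excluded for any of these effects.

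Sex of the cultures might carry part of the genotype calls, as Xist and Eif2s3y divide the arrays unevenly between groups. With sex as a covariate, 52.8% of the 176 average genotype calls (93 genes) stayed past the threshold. The bounds set beforehand were 50% and 80%, so the test left this open, and cultures of known sex would settle it.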
